A study of Homo sapiens with 8 samples.

How the data were processed

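Total RNA from 2 human T-cell acute lymphoblastic leukaemia (T-ALL) cell lines, DND-41 and MOLT-4, was sequenced as strand-specific paired-end libraries, per the labels' protocols. Cells of each line had been treated for 3 h with 100 nM ACBI-1 or with DMSO, the solvent control. Every library was assigned to its line, treatment and replicate number from its title in the labels, which gave 4 groups of 2 libraries. The labels do not say whether the 2 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

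The authors deposited 1 table of raw read counts per line, with 63677 annotated genes in each, and these counts carried no normalization. They were scaled to a common library size for display, as CPM. STAR 2.5.2a, featureCounts, DESeq2 1.12.4 and the build hg19 are named in the submitters' processing notes, without a role or an order. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene could not be separated from those of an overlapping or antisense gene, and a gene with a near-identical copy may share reads with it. The authors also deposited 1 table per line of their own comparison, with a log2 fold change, its standard error, a p-value and an adjusted p-value for each gene, per the file headers. The direction of the sign in these deposited tables is not stated in the headers, and was read from the correlation of their log2 fold changes with those computed from the counts. No spike-in is named in the labels, so all values are relative to the total of each library.

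Total counts lay between 19867779 and 20082524 per library. At this depth a gene at 1 CPM had about 20 reads in a library, and a count of 0 allows up to 3 reads at the 95% upper limit, counting error only. No pair of replicates agreed within sampling noise, as the chi-square of their counts averaged between 3.19 and 17.2 per gene over the 4 groups, so all 8 libraries were counted as separate samples. All sample columns of the deposited count tables were matched to the labels.

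Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with the quasi-likelihood F-test after trimmed mean of M-values (TMM) scaling and the default filter on low counts (filterByExpr). Each line was fitted on its own 4 libraries, as 2 ACBI-1 against 2 DMSO libraries, with no covariate. The difference between the responses of the lines was the interaction of treatment and line in a fit of all 8 libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 5%. Every adjusted p given for a gene comes from this edgeR test unless another tool is named. Log2 fold changes are ACBI-1 minus DMSO and are given with their standard error (SE), and CPM values with the SD over n = 2 libraries. No exact permutation test of 2 against 2 libraries can reach 0.05, so none was used.

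Of 27 gene lists fixed in advance, 26 had at least 3 tested members in each line and were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the lists. The same lists were tested with a correlation estimated from the data and with fry. Counts of changed members are given over all genes tested and also adjusted over the list alone. The genes to be named were also fixed by rule. Per line these were the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM and with both ACBI-1 libraries on the same side of both DMSO libraries. For genes changed the same way in both lines, and for the difference between lines, these were the 5 largest in each direction with a mean of at least 5 CPM over the 2 lines together, so a gene could lie below that in 1 line. From each list described up to 4 members with the smallest p were taken, and 17 regulators and targets were always reported. Entries without a gene symbol were passed over, and some genes that these rules chose are not reported here. The tests, the lists, the rule for named genes and a first set of alternatives were chosen before the data were examined.

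That first set held the estimated correlation and fry for the lists, and for the genes DESeq2 (1.42.0), its size factors within edgeR, scaling by total counts, no filter on low counts, a threshold of 1%, a minimum fold of 1.5 (glmTreat), the replicate number as a block, all 8 libraries in one fit, and leaving out each library in turn. Chosen after seeing the data were a correction for the GC content of transcripts, the subtraction of MOLT-4 reads from 1 DND-41 library, the removal of genes at least 10 times higher in MOLT-4, and leaving out each library in the fit of all 8. The GC correction removed a smooth trend with 6 degrees of freedom per library. GC content and transcript length came from GENCODE release 29, matched by Ensembl identifier for 97.1% of the genes tested in DND-41 and 97.3% of those tested in MOLT-4. That annotation is on another build than the counts, so it was used for these properties only and no coordinates are given.

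The scripts were tested on simulated data in which 200 genes changed. For DND-41 (14036 genes) edgeR recovered 74.6%, 89.2% and 98.5% of the genes changed by 1.5, 2 and 3 times, and 2.26% of its calls were false. For MOLT-4 (14422 genes) the shares were 67.2%, 86.4% and 97.0%, with 5.68% false. For the difference between lines (15602 genes) they were 49.3%, 75.8% and 76.2%, with 4.38% false. These runs held no GC trend. With a GC trend added to 1 ACBI-1 library, edgeR recovered 56.7%, 81.8% and 93.9% in DND-41, with 0% false. In MOLT-4 it then recovered 56.7%, 75.8% and 96.9%, with 0.658% false. After the GC correction, the shares for 1.5 times were 71.6% in DND-41 and 64.2% in MOLT-4. With no gene changed, no gene was called in either line. A list shifted by 0.3 on the log2 scale was called by camera with the preset correlation in both lines, but not with an estimated correlation, where its adjusted p was 0.228 in DND-41 and 0.241 in MOLT-4. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.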

Results

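Gene expression was measured by RNA sequencing in DND-41 and MOLT-4 cells, both established T-ALL lines, after 3 h with 100 nM ACBI-1 or DMSO. ACBI-1 is a bifunctional degrader that brings the VHL ubiquitin ligase to SMARCA2 and SMARCA4, the ATPases of the SWI/SNF (BAF) chromatin remodelling complex, and to PBRM1, a subunit of its PBAF form. Each of the 4 groups held 2 libraries, with total counts between 19867779 and 20082524. Mitochondrially encoded genes took between 13.3% and 20.04% of the counts. The lines differed in their leukaemic transcription factors: TLX3, a homeobox oncogene, had between 4611 and 7523 counts in the DND-41 libraries and at most 9 in MOLT-4, while TAL1, a basic helix-loop-helix oncogene, had between 722 and 796 counts in MOLT-4 and at most 4 in DND-41.

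The degrader acts on proteins, which were not measured here. The transcripts of its targets were not called in either line. In DND-41 the log2 fold change was -0.13 ± 0.08 for SMARCA2, 0.06 ± 0.07 for SMARCA4 and 0.06 ± 0.07 for PBRM1, and in MOLT-4 it was -0.07 ± 0.09, 0.05 ± 0.07 and -0.13 ± 0.06. VHL was at -0.01 ± 0.07 in DND-41 and -0.02 ± 0.07 in MOLT-4. With these transcripts 0 of 4 members of the list of targets and ligase changed in either line, over all genes or adjusted over the list alone. In DND-41 the median of that list was 0.02 and its test upward while its mean was -0.01.

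The first comparison asked which transcripts changed within 3 h of ACBI-1 in DND-41. ID3 (ENSG00000117318), an inhibitor of E-protein transcription factors, rose from 55.7 ± 2.97 to 134 ± 15.6 CPM (SD, n = 2), a log2 fold change of 1.27 ± 0.08 (edgeR, adjusted p = 7.00e-14). HES1 (ENSG00000114315), a repressor induced by Notch signalling, fell from 69.0 ± 2.12 to 23.6 ± 3.06 CPM (-1.54 ± 0.09, edgeR adjusted p = 7.00e-15), and the chemokine receptor gene CXCR4 fell from 218 ± 0.36 to 90.4 ± 2.30 CPM (-1.27 ± 0.07). DLX1, a homeobox transcription factor, fell from 17.3 ± 0.25 to 4.43 ± 0.49 CPM (-1.96 ± 0.13).

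Other rises in DND-41 were VPS37C, a subunit of the ESCRT-I sorting complex (1.47 ± 0.12), the prostaglandin receptor gene PTGDR2 (1.39 ± 0.12), CPEB4, a regulator of translation (1.19 ± 0.18), ZP1 (1.18 ± 0.12), the zinc finger gene ZNF341 (1.13 ± 0.10) and C2CD4B (1.04 ± 0.08). Falls were seen in TAGAP, a gene of T-cell activation (-1.39 ± 0.14), BBC3, which encodes the pro-apoptotic protein PUMA (-1.38 ± 0.16), C16orf54 (-1.19 ± 0.12) and STAT5A (-1.17 ± 0.18), a transducer of cytokine signals. MTND1P23, a pseudogene with a near-identical mitochondrial copy, had the largest fitted fall (-2.73 ± 0.50), but its DMSO libraries held 1.96 and 20.3 CPM and the call was lost with DESeq2 (adjusted p = 0.333). MTND1P23 and STAT5A are among the 48 MOLT-4 markers described below, whose reads were found in DMSO replicate 2 (below 1% of their MOLT-4 level at the median). MTND1P23 stood at 0.712% of its MOLT-4 level in that library, and at 0.0548% to 0.0691% in the other DND-41 libraries. Without DMSO replicate 2 the result for MTND1P23 in DND-41 was -0.23 and that for STAT5A in DND-41 was -0.77. Among the regulators always reported, TLX3 fell (-0.54 ± 0.07), as did CDKN1A, the gene of the cell-cycle inhibitor p21 (-0.70 ± 0.11), and the survival genes MCL1 (-0.42 ± 0.07) and BCL2 (-0.30 ± 0.07). MYC rose (0.30 ± 0.09) and so did MYB (0.22 ± 0.07), both leukaemic transcription factors, although MYB in DND-41 was not called with scaling by total counts (adjusted p = 0.0571) or in the fit of all 8 libraries (adjusted p = 0.0598). NOTCH1 was at -0.0028 ± 0.09, GATA3 at -0.05 ± 0.07, RUNX1 at 0.04 ± 0.07 and BCL11B at -0.19 ± 0.07, none of them called. LMO2 had no counts in DND-41.

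Of the gene lists, cholesterol synthesis and SREBP2 targets were higher in DND-41. Of 23 tested members 11 rose and none fell (14 and 0 adjusted over the list alone), with a median of 0.26 (camera, adjusted p = 4.88e-06; adjusted p = 0.634 with an estimated correlation). They included MVD (0.51 ± 0.07) and MVK (0.50 ± 0.07), enzymes of the mevalonate pathway, and DHCR7 (0.40 ± 0.07), which completes sterol synthesis. MYC-linked ribosome biogenesis genes were also higher, with 5 of 30 risen and 0 fallen (6 and 0 adjusted over the list alone) and a median of 0.13 (camera, adjusted p = 0.00327; adjusted p = 0.634 with an estimated correlation). Without DMSO replicate 1 that list's adjusted p was 0.0651. Its leading members were POLR1B, a subunit of RNA polymerase I (0.27 ± 0.07), and the rRNA processing factors RRS1 (0.29 ± 0.08), RRP12 (0.24 ± 0.07) and WDR43 (0.22 ± 0.07), and DESeq2 called none of these 4. Immediate early genes were lower, with 2 of 32 risen and 11 fallen (3 and 12 adjusted over the list alone) and a median of -0.19 (camera, adjusted p = 0.00253; adjusted p = 0.634 with an estimated correlation). Without ACBI-1 replicate 1 its adjusted p was 0.101. IER3 fell (-2.06 ± 0.22), as did ZFP36, an RNA-destabilising protein (-0.77 ± 0.09), and JUND, an AP-1 subunit (-0.56 ± 0.07), while BTG1, an antiproliferative gene, rose (0.64 ± 0.07).

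No other list was called in DND-41, although members of several changed. Of 14 NOTCH1 target genes 1 rose and 4 fell (3 and 6 adjusted over the list alone; camera, adjusted p = 0.145), with DTX1, a regulator of Notch signalling, at -0.40 ± 0.09. Of 25 p53 target genes 2 rose and 6 fell (3 and 8 over the list alone; adjusted p = 0.317). Among them SESN2, a stress-induced inhibitor of growth signalling, fell (-0.92 ± 0.08) and PLK2, a kinase gene, rose (2.02 ± 0.26). PLK2 had few reads in DND-41, with 1.01 CPM in DMSO. Of 22 hypoxia targets 0 rose and 6 fell (0 and 6; adjusted p = 0.0767), including BHLHE40, a transcriptional repressor (-0.50 ± 0.08), EGLN3, an oxygen-sensing hydroxylase (-0.68 ± 0.12), and the angiogenic factor VEGFA (-0.39 ± 0.07). Of 20 cytokine receptor and JAK-STAT feedback genes 1 rose and 5 fell (5 and 11; adjusted p = 0.0726), with SOCS2, a feedback inhibitor, at -0.50 ± 0.07. NF-kB targets showed 3 rises and 6 falls in 19 (3 and 7; adjusted p = 0.2), the BCL2 family 2 and 4 in 13 (3 and 4; adjusted p = 0.14), T-ALL transcription factors 2 and 4 in 20 (3 and 5; adjusted p = 0.56) and TAL1-regulated genes 2 and 2 in 13 (2 and 3; adjusted p = 0.611). TNF, a cytokine gene of the NF-kB list, fell (-1.06 ± 0.10) and REL, an NF-kB subunit, rose (0.95 ± 0.11). BCL2L11, the gene of the pro-apoptotic protein BIM, rose (0.52 ± 0.07), and FLI1, an ETS transcription factor, fell (-0.59 ± 0.07).

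The SWI/SNF (BAF) subunit list had 2 rises and 1 fall among 28 genes in DND-41 (2 and 1 adjusted over the list alone; camera, adjusted p = 0.797), led by GLTSCR1L, a subunit of the non-canonical BAF complex (0.59 ± 0.08). Of 19 other chromatin remodellers 0 rose and 1 fell (0 and 1; adjusted p = 0.611), the NuRD ATPase gene CHD4 (-0.58 ± 0.07). T-cell receptor and thymocyte genes had 4 rises and 1 fall in 34 (4 and 2; adjusted p = 0.611), interferon-stimulated genes 3 and 1 in 24 (6 and 4; adjusted p = 0.611), the unfolded protein and amino acid stress response 0 and 5 in 25 (1 and 5; adjusted p = 0.0726), and G2 and mitosis genes 1 and 2 in 30 (2 and 4; adjusted p = 0.0726). There was 1 fall among 33 DNA replication and G1/S genes (adjusted p = 0.887) and 1 among 19 heat shock genes (adjusted p = 0.56), each also 1 over the list alone. BET bromodomain and elongation genes had 1 rise and 1 fall in 21 (1 and 1; adjusted p = 0.906). None of 40 ribosomal protein genes (adjusted p = 0.335), 14 replication-dependent histones (adjusted p = 0.653), 13 mitochondrially encoded genes (adjusted p = 0.887) or 6 B-cell markers (adjusted p = 0.56) changed, over all genes or over the list alone. The median of the mitochondrially encoded genes was 0.02, but -0.21 without ACBI-1 replicate 1, and its sign depended on the library left out. Their share of counts was 17.4% in ACBI-1 replicate 1 and 13.3% in ACBI-1 replicate 2. Of 3 epithelial and fibroblast markers 1 fell (2 over the list alone; adjusted p = 0.066), the receptor gene PDGFRB (-0.62 ± 0.09), and myeloid and erythroid markers had too few tested members for a test in either line. The DNA replication list had a median of 0.0090 with a mean of -0.02 and a downward test, and the BET list a median of 0.0047 with a mean of -0.0043 and an upward test.

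In all, 1378 of 14019 genes tested in DND-41 passed the threshold (edgeR quasi-likelihood, Benjamini-Hochberg), of which 530 rose and 848 fell. The change was at least 2-fold for 99 of them, 40 rising and 59 falling. The count was 664 with DESeq2, 2 without the filter on low counts, and 3, 177, 610 and 632 when ACBI-1 replicate 1, ACBI-1 replicate 2, DMSO replicate 1 or DMSO replicate 2 was left out. In a fit that shared the spread with the MOLT-4 libraries it was also 1378, but not for the same genes. There 438 rose and 940 fell, and 1262 of these genes were called in both fits. With the GC correction, chosen after seeing the data, 770 rose and 907 fell, so the share of falls was 54.1% against 61.5%.

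**Figure D1:**
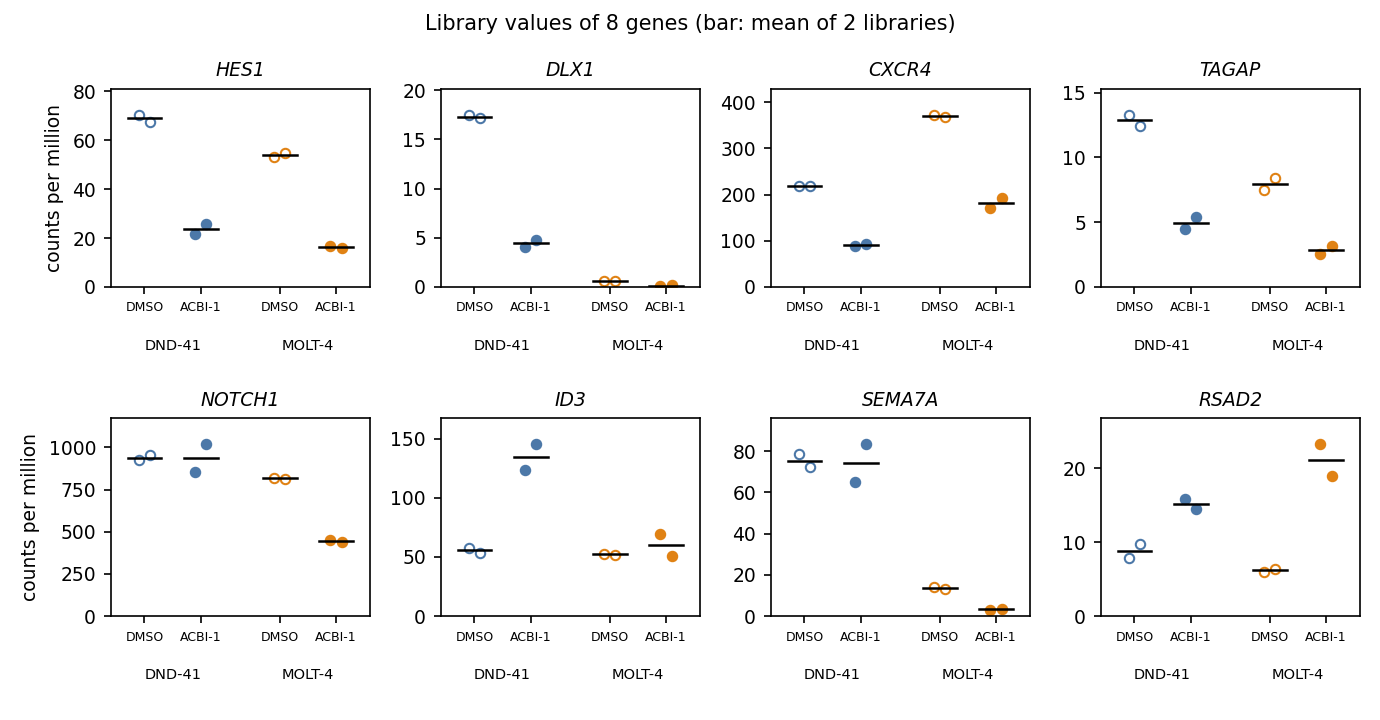
CPM of 8 genes in each library, with open circles for DMSO, filled circles for ACBI-1, blue for DND-41, orange for MOLT-4 and a bar at the mean of the 2 libraries. HES1, CXCR4 and TAGAP were lower with ACBI-1 in both lines, while the rise of ID3 was seen in DND-41 and the falls of NOTCH1 and SEMA7A in MOLT-4.

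The second comparison asked the same of MOLT-4. HES1 fell from 54.1 ± 1.18 to 16.3 ± 0.81 CPM (SD, n = 2), a log2 fold change of -1.73 ± 0.08 (edgeR, adjusted p = 1.04e-13). NOTCH1 (ENSG00000148400), the receptor gene often mutated in T-ALL, fell from 816 ± 5.23 to 445 ± 7.31 CPM (-0.88 ± 0.06, edgeR adjusted p = 1.59e-10). SEMA7A, a membrane-bound semaphorin, fell from 13.7 ± 0.49 to 3.32 ± 0.36 CPM (-2.04 ± 0.15), and PDCD1, the gene of an inhibitory T-cell receptor, from 16.9 ± 2.75 to 4.66 ± 0.31 CPM (-1.86 ± 0.14). RSAD2, an interferon-induced antiviral gene, had the largest rise, from 6.18 ± 0.33 to 21.1 ± 3.07 CPM (1.77 ± 0.13, edgeR adjusted p = 1.95e-10). All of these calls were lost when either ACBI-1 library was left out of the MOLT-4 fit.

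Further rises in MOLT-4 were GCNT1, a glycosyltransferase (1.26 ± 0.13), the synaptotagmin gene SYT11 (1.195 ± 0.17), the deubiquitinase gene OTUB2 (1.09 ± 0.17), FPGT (1.02 ± 0.16), ZNF333 (0.98 ± 0.09), ARMC2 (0.98 ± 0.17) and MSMO1, a sterol synthesis enzyme (0.97 ± 0.08). Further falls were CECR6 (-1.84 ± 0.17), FGFRL1, a receptor-like protein that binds fibroblast growth factors (-1.77 ± 0.12), the centriole gene HYLS1 (-1.66 ± 0.16), the growth factor gene BMP4 (-1.57 ± 0.16) and the glycosyltransferase gene B3GNT9 (-1.57 ± 0.17). Among the regulators always reported, LMO2, a partner of TAL1, fell (-1.49 ± 0.22), as did GATA3 (-0.48 ± 0.06), the T-lineage factor BCL11B (-0.38 ± 0.07) and MCL1 (-0.50 ± 0.07). MYC (0.35 ± 0.06) and MYB (0.22 ± 0.06) rose. TAL1 was at 0.07 ± 0.08, RUNX1 at 0.08 ± 0.06, BCL2 at -0.20 ± 0.11 and CDKN1A at -0.23 ± 0.25, none of them called.

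Cholesterol synthesis and SREBP2 targets were higher in MOLT-4 as well. Of 23 tested members 18 rose and none fell (20 and 0 adjusted over the list alone), with a median of 0.34 (camera, adjusted p = 3.21e-10; adjusted p = 0.451 with an estimated correlation). MSMO1 led, and MVK (0.73 ± 0.08) and MVD (0.58 ± 0.07) also rose. Immediate early genes were lower, with 2 of 35 risen and 11 fallen (4 and 15 adjusted over the list alone) and a median of -0.28 (camera, adjusted p = 0.00367; adjusted p = 0.696 with an estimated correlation). Here KLF10, a zinc finger repressor, fell (-1.55 ± 0.08), with ZFP36 (-0.69 ± 0.08), the phosphatase gene DUSP2 (-1.0004 ± 0.12) and JUND (-0.50 ± 0.06). p53 target genes were lower, with 1 of 25 risen and 6 fallen (2 and 6 adjusted over the list alone) and a median of -0.13 (camera, adjusted p = 0.0463; adjusted p = 0.696 with an estimated correlation). That call was lost without ACBI-1 replicate 2 (adjusted p = 0.114) or DMSO replicate 1 (adjusted p = 0.0737). The death receptor gene FAS fell (-0.92 ± 0.13), as did PMAIP1, which encodes the pro-apoptotic protein NOXA (-0.60 ± 0.11), and PHLDA3 (-0.96 ± 0.19), an inhibitor of AKT.

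**Figure D2:**
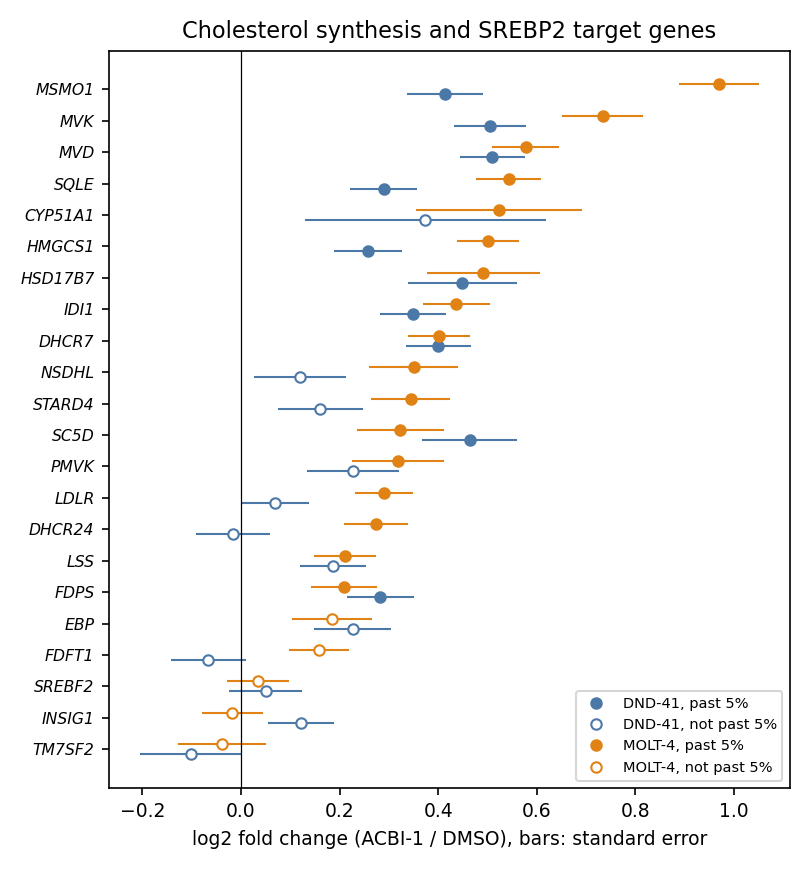
Log2 fold changes with standard errors of 22 of the 23 tested genes of the cholesterol synthesis list in DND-41 and MOLT-4, with filled circles for genes past the 5% threshold. Of all 23 none fell past the threshold, and 11 rose in both lines.

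No other list was called in MOLT-4. Of 15 NOTCH1 target genes 3 rose and 5 fell (3 and 7 adjusted over the list alone; camera, adjusted p = 0.107), with DTX1 at -1.33 ± 0.11 and FJX1 at -1.81 ± 0.25 beside HES1 and NOTCH1. Of 24 T-ALL transcription factors 5 rose and 8 fell (5 and 9; adjusted p = 0.145), among them SATB1, a chromatin organiser (-0.54 ± 0.06), and ETS1 (0.46 ± 0.06). Of 23 hypoxia targets 0 rose and 5 fell (0 and 5; adjusted p = 0.145), with BHLHE40 at -1.29 ± 0.11, DDIT4, an inhibitor of mTOR signalling, at -1.06 ± 0.11 and the glucose transporter gene SLC2A3 at -0.81 ± 0.15. Of 35 T-cell receptor and thymocyte genes 3 rose and 7 fell (4 and 8; adjusted p = 0.422), including the surface receptor CD5 (-0.54 ± 0.06) and LAT, an adaptor of T-cell receptor signalling (-0.71 ± 0.09). Of 21 cytokine receptor and JAK-STAT genes 2 rose and 6 fell (2 and 7; adjusted p = 0.114), with the kinase JAK3 at -0.70 ± 0.07 and STAT5A at 0.46 ± 0.07. MYC-linked ribosome biogenesis had 3 rises and 2 falls in 30 (3 and 2; adjusted p = 0.0592), the BCL2 family 2 and 5 in 14 (3 and 6; adjusted p = 0.114), NF-kB targets 2 and 4 in 15 (2 and 4; adjusted p = 0.173), and TAL1-regulated genes 3 and 3 in 16 (4 and 5; adjusted p = 0.888).

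None of 28 SWI/SNF (BAF) subunit genes changed in MOLT-4, over all genes or adjusted over the list alone (camera, adjusted p = 0.829). Of 19 other chromatin remodellers 1 rose and 2 fell (1 and 2; adjusted p = 0.629), with CHD4 at -0.63 ± 0.06. Interferon-stimulated genes had 4 rises and 1 fall in 24 (5 and 2; adjusted p = 0.238), the unfolded protein and amino acid stress response 1 and 4 in 26 (1 and 4; adjusted p = 0.829), and DNA replication and G1/S 2 and 2 in 34 (2 and 2; adjusted p = 0.629). Of 18 heat shock genes 0 rose and 4 fell (0 and 4; adjusted p = 0.145), among them the co-chaperone gene BAG3 (-0.57 ± 0.10). None of 30 G2 and mitosis genes changed (adjusted p = 0.0696), nor of 4 epithelial and fibroblast markers (adjusted p = 0.629), again on both counts. BET bromodomain and elongation genes had 1 rise and 1 fall in 22 (1 and 1; adjusted p = 0.629), and mitochondrially encoded genes 0 and 2 in 13 (0 and 5; adjusted p = 0.107). There was 1 fall among 40 ribosomal protein genes (0 over the list alone; adjusted p = 0.0983), 1 among 19 replication-dependent histones (0; adjusted p = 0.502) and 1 among 5 B-cell markers (1; adjusted p = 0.728). Median, mean and test differed in sign for TAL1-regulated genes (median 0.0010, mean -0.03, test downward), DNA replication (0.01, -0.02, upward), the unfolded protein response (0.0097, -0.03, downward) and BET genes (-0.00036, 0.02, upward).

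In all, 1568 of 14470 genes tested in MOLT-4 passed the threshold (edgeR quasi-likelihood, Benjamini-Hochberg), of which 564 rose and 1004 fell. The change was at least 2-fold for 169 of them, 37 rising and 132 falling. The count was 754 with DESeq2, 39 without the filter on low counts, and 0 without ACBI-1 replicate 1 or ACBI-1 replicate 2, when 1874 and 2273 genes still had an unadjusted p under 0.05, and the fit of all 8 libraries called 725 and 712. With the GC correction, chosen after seeing the data, 886 rose and 1016 fell, so the share of falls was 53.4% against 64.0%.

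The third comparison asked whether the lines responded alike. HES1 and TAGAP fell in both, as did HYLS1 (-1.54 ± 0.18 in DND-41 and -1.66 ± 0.16 in MOLT-4), DLX1 (-1.96 ± 0.13 and -2.24 ± 0.60) and RGS16, a regulator of G-protein signalling (-1.16 ± 0.12 and -1.35 ± 0.37). In MOLT-4 DLX1 and RGS16 were close to the lower limit of detection, at 0.367 and 1.11 CPM. The largest shared rises were ZNF333 (0.84 ± 0.09 and 0.98 ± 0.09), ZNF341 (1.13 ± 0.10 and 0.83 ± 0.08), CTTN, an actin-binding protein (0.83 ± 0.14 and 0.87 ± 0.17), VPS37C (1.47 ± 0.12 and 0.83 ± 0.09) and N6AMT1, a methyltransferase (1.03 ± 0.11 and 0.79 ± 0.11). Of the cholesterol synthesis genes 11 rose in both lines, and 7 immediate early genes fell in both, namely CSRNP1, DUSP2, DUSP5, IER2, IER3, JUND and ZFP36.

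Of 12968 genes tested in both lines, 208 rose in both, where 20.6 would be shared by independent lists of 506 and 528 genes (Fisher's exact test, p = 9.97e-166, 2-sided). Another 431 fell in both, where 54.7 would be shared by lists of 799 and 887, and 16 changed in opposite directions. Across genes the log2 fold changes had a Pearson r of 0.44 and a Spearman rho of 0.46. Genes are not independent replicates, so these values are descriptions. The count of 639 genes changed the same way was 292 with DESeq2, 1 without the filter on low counts, 1, 130, 349 and 371 without DND-41 ACBI-1 replicate 1, ACBI-1 replicate 2, DMSO replicate 1 or DMSO replicate 2, and 0 without either MOLT-4 ACBI-1 library, when edgeR called no gene in MOLT-4. The r was 0.17 in the fit of all 8 libraries and 0.02 without the filter, both over more genes.

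**Figure D3:**
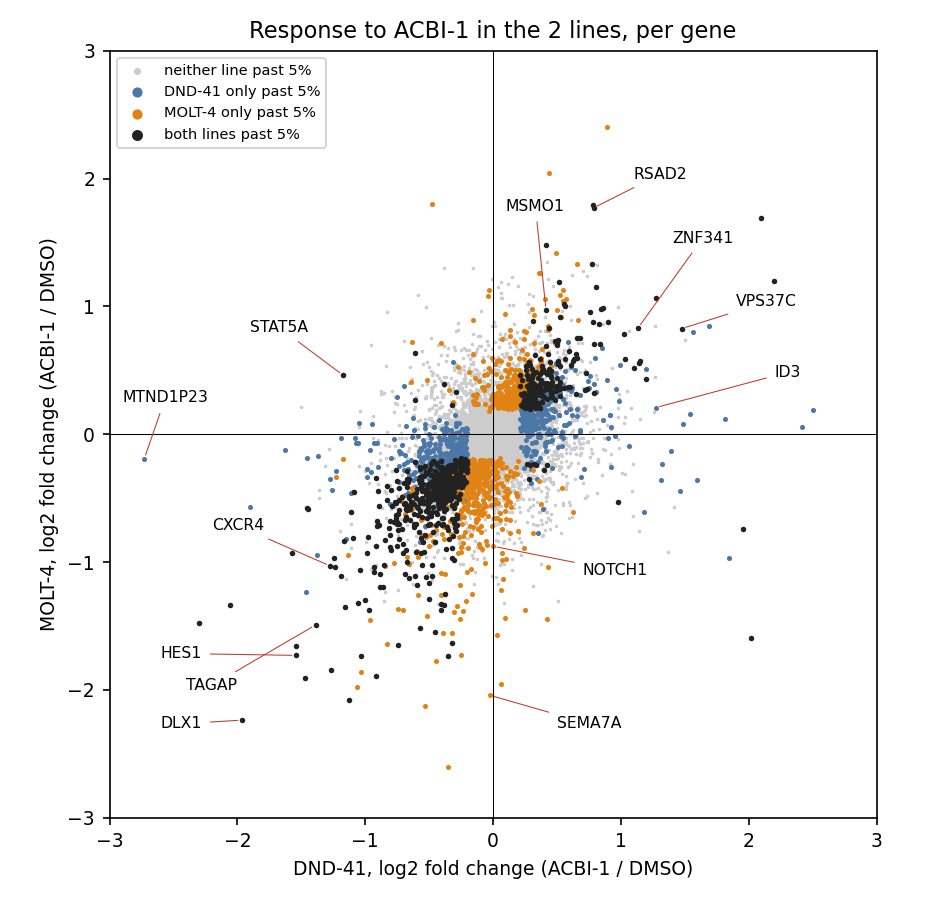
Log2 fold change with ACBI-1 in DND-41 (horizontal) and MOLT-4 (vertical) for the 12968 genes tested in both, coloured by the line or lines in which the gene passed the 5% threshold. Most genes past the threshold in both lines lie in the lower left and upper right quadrants, with 639 in the same and 16 in opposite directions.

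The difference between the responses was then tested gene by gene. SEMA7A fell in MOLT-4 and was at -0.02 in DND-41, a difference (MOLT-4 minus DND-41) of -1.998 ± 0.18 (edgeR interaction, adjusted p = 2.16e-07), and NOTCH1 fell in MOLT-4 (difference -0.85, with DND-41 at -0.0028). STAT5A fell in DND-41, where it had 10.2 CPM in DMSO, and rose in MOLT-4, where it had 707 CPM (difference 1.66 ± 0.20, adjusted p = 3.62e-05). STAT5A is itself among the 48 MOLT-4 markers. Its DND-41 DMSO libraries held 7.77 and 12.8 CPM, the higher in replicate 2 with its MOLT-4 marker reads. Without that library the STAT5A difference between lines was 1.25. FOXB1, a forkhead transcription factor, fell in DND-41 and rose in MOLT-4 (1.27 ± 0.17). PTGDR2 (-1.50 ± 0.21) and ZP1 (-1.76 ± 0.35) rose in DND-41 and were not called in MOLT-4, and CD248, the endosialin gene, fell in MOLT-4 and was not called in DND-41 (-1.44 ± 0.34).

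The largest differences in favour of MOLT-4 were ITM2A (3.94 ± 0.93), the T-cell receptor segment TRBV20-1 (3.92 ± 0.90) and ALDH1A2 (3.33 ± 0.79), genes with 358, 892 and 223 CPM in MOLT-4 DMSO and a mean of at most 2.58 CPM in either DND-41 group. In 1 of the DND-41 libraries, DMSO replicate 2, markers of MOLT-4 stood at a median of 0.705% of their MOLT-4 level, against 0.0531% to 0.0936% in the other 3 DND-41 libraries. These 3 genes are among those markers, so their loss of the threshold after subtraction of MOLT-4 reads, chosen after seeing the data, does not settle their source. Their reads in DND-41 lay mostly in DMSO replicate 2, on which these differences rest. In all, 100 of 15604 genes differed between the lines (edgeR interaction, Benjamini-Hochberg), 31 higher and 69 lower in MOLT-4. Of these, 14 were called in both lines in the same direction, 16 in opposite directions, 18 in DND-41 alone, 49 in MOLT-4 alone and 3 in neither. With the replicate number as a block 302 genes differed, 126 higher and 176 lower in MOLT-4. The count was 92 with DESeq2, 13 without the filter on low counts, and 58, 52, 49 and 64 without DND-41 DMSO replicate 2, MOLT-4 ACBI-1 replicate 1, MOLT-4 ACBI-1 replicate 2 or MOLT-4 DMSO replicate 2. Without DND-41 DMSO replicate 1 the balance turned, with 53 higher and 46 lower in MOLT-4.

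**Figure D4:**
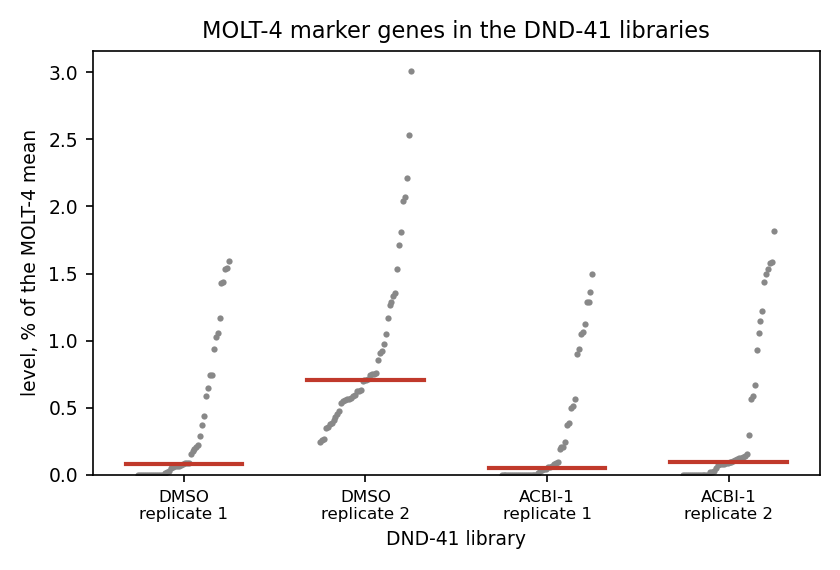
Levels of 48 MOLT-4 marker genes in each DND-41 library, as a percentage of their MOLT-4 level, with grey points for the genes in order of level and a red bar for the median. DMSO replicate 2 has a median of 0.705%, and 45 of the 48 markers are highest in it.

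The authors' deposited tables were compared with these fits. The deposited log2 fold changes are ACBI-1 minus DMSO for DND-41 and DMSO minus ACBI-1 for MOLT-4, with a correlation across genes of 0.99998 and -0.99998 with the values above. At the same threshold the authors' deposited table held 603 genes for DND-41, 197 higher and 406 lower with ACBI-1, and 598 of them were also called with edgeR. For MOLT-4 the authors' deposited table held 696 genes, 224 higher and 472 lower with ACBI-1 once its sign was turned, and 694 of them were also called with edgeR. In the authors' deposited table NOTCH1 in MOLT-4 stood at 0.87 and HES1 at 1.72, which are falls with ACBI-1 in the orientation used here.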

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

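Of the tests in this part, the GC correction and the subtraction of MOLT-4 reads were chosen only after the results were seen. So was the test of the cholesterol synthesis list for a difference between lines. The test of expression levels and the matched random lists were set before their results.

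The response to ACBI-1 differed between DND-41 and MOLT-4 for 100 genes in the edgeR interaction test, and 28 genes named here were among them, 19 lower and 9 higher in MOLT-4. All differences below are log2 fold changes in MOLT-4 minus those in DND-41. Genes that rose in DND-41 and did not rise as far in MOLT-4 were PLK2 (-3.58, rising in DND-41 from 1.01 CPM and falling in MOLT-4, where it had under 1 CPM), ZP1 (-1.76), PTGDR2 (-1.50), ID3 (-1.04), REL (-0.94), BTG1 (-0.63) and GIMAP5 (-0.62). Genes that fell in MOLT-4 and fell less, or did not fall, in DND-41 were SEMA7A (-1.998), B3GNT9 (-1.58), CD248 (-1.44), KLF10 (-1.21), the Notch genes DTX1 (-0.90) and NOTCH1 (-0.85), the stress and hypoxia genes DDIT4 (-0.86) and BHLHE40 (-0.76), the cytokine gene LTB (-0.79), the kinase gene PIM1 (-0.58) and the T-lineage regulators SATB1 (-0.44) and GATA3 (-0.40). Higher in MOLT-4 by this measure were STAT5A (1.66), FOXB1 (1.27), RSAD2 (1.01), SESN2 (0.60), MSMO1 (0.58), HERPUD1, an endoplasmic reticulum stress gene (0.55), ITM2A (3.94), TRBV20-1 (3.92) and ALDH1A2 (3.33). GATA3 was not called with scaling by total counts, where the result of the GATA3 difference between lines had an adjusted p of 0.0621.

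Of these 100 genes, 96% had at least 1 CPM in the DMSO libraries of both lines, against 74.5% of all genes tested. A level under 1 CPM in 1 line was thus not a trait of most of them. Genes with few reads are also less likely to be called, so this share does not exclude low expression as a source. The 96% include ITM2A and TRBV20-1, whose DND-41 DMSO means of 1.44 and 2.58 CPM came mostly from replicate 2. A GC trend between libraries as the whole cause is argued against, since all 100 stayed past the threshold after the correction. MOLT-4 reads in DND-41 DMSO replicate 2 left 96 of the 100 past the threshold after subtraction, and so may explain at most a small part. That part holds ITM2A, TRBV20-1 and ALDH1A2, of which 0 of 3 stayed past the threshold, with 2.10 ± 0.83 for the ITM2A difference between lines, -1.08 ± 0.97 for the TRBV20-1 difference between lines and 1.60 ± 0.76 for the ALDH1A2 difference between lines, against 3.94 ± 0.93, 3.92 ± 0.90 and 3.33 ± 0.79. ITM2A, TRBV20-1 and ALDH1A2 stood at 0.756%, 0.565% and 0.707% of their MOLT-4 level in DND-41 DMSO replicate 2. In DMSO replicate 1 they stood at 0.0271%, 0.0169% and 0.0861%, and in the DND-41 ACBI-1 libraries at no more than 0.0860%. Their differences between lines thus rest on DMSO replicate 2. These 3 genes are among the 48 markers that gave the subtracted share, so the subtraction cannot decide the source of their reads, which stays open. A difference between the lines in how they respond to ACBI-1 stays open as a hypothesis for the others, found and tested on the same libraries.

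The cholesterol synthesis list rose further in MOLT-4 than in DND-41, with a median difference of 0.12 (camera, adjusted p = 0.0349; adjusted p = 0.623 with an estimated correlation). For its rise in both lines, a GC trend between libraries is argued against by the median of at least 0.27 that it kept after the correction. The GC content, length and expression level of its members are argued against by random lists of genes matched on all of these, as the list's median lay at percentile 100 of 10000 such lists in both lines. Fry, which asks another question, also called the list upward, with an adjusted p of 0.00586 in DND-41 and 0.0107 in MOLT-4. The camera call rests on the preset correlation between genes, and with an estimated one the camera adjusted p was 0.634 in DND-41 and 0.451 in MOLT-4. A simulated list shifted by 0.3 was not called with an estimated correlation either. Its genes were drawn independently of each other, so that simulation cannot tell which correlation is right for the real list. It does show that the test with an estimated correlation can miss a true shift of 0.3. The lack of a call there thus does not by itself count against the list. A response of sterol synthesis genes to ACBI-1 is a hypothesis that these tests leave open, and with 2 libraries per group a shared difference in the cultures would look alike.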

How the results depend on the processing

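The alternatives with a GC correction, subtracted MOLT-4 reads, genes 10 times higher in MOLT-4 removed, and libraries left out of the fit of all 8 were chosen only after seeing the data. With DESeq2 the count of changed genes was 664 in DND-41 and 754 in MOLT-4 with 292 shared, at a threshold of 1% it was 763 and 879, and with a minimum fold of 1.5 it was 35 and 74. Without the filter on low counts it was 2 and 39 with 1 shared, 13 genes differed between the lines and r was 0.0203. More low genes were then tested, and the prior degrees of freedom of the spread fell to 3.12 and 2.898 from 30.7 and 23.5. The fit of all 8 libraries gave 1378 and 1397 genes, of which 1262 and 1375 were also called in the fits per line, and an r of 0.17. It kept 15604 genes for each line, so its r covers more genes than the 12968 tested in both lines by the separate fits. How far these added genes lower r was not tested. No list was called in either line with an estimated correlation, which also missed the simulated shift of 0.3. Fry, which asks another question, called 1 list in each line, the cholesterol synthesis list in both. Scaling by total counts called 5 lists in MOLT-4. The size factors of DESeq2, scaling by total counts, the GC correction and, where they applied, the subtraction of MOLT-4 reads and the removal of MOLT-4 genes kept the total of genes called in each comparison within 1.5 times, and r moved from 0.44 to at most 0.45.

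To look for pairing, the log2 difference of replicate 2 minus replicate 1 was taken in DMSO and in ACBI-1. Across all genes these 2 differences correlated at 0.07 in each line. Over genes of at least 5 CPM they correlated at 0.198 in DND-41 and 0.163 in MOLT-4 (0.0982 and 0.123 after the GC correction). Over genes of at least 5 CPM with a known GC content, these differences trended with GC content in the same direction in both arms. The Spearman rho was 0.278 in DMSO and 0.498 in ACBI-1 for DND-41, and -0.180 and -0.347 for MOLT-4. Trends with transcript length also had the same sign in both arms of each line. Such shared trends would go with pairing. The labels give no meaning to the replicate number, and 2 pairs per line are too few to settle whether libraries were paired, so they were not treated as paired. With the replicate number as a block the counts were 2230 genes in DND-41, 2228 in MOLT-4, 1001 in both and 302 for the difference, with 5 lists called in MOLT-4. In these fits the prior degrees of freedom were infinite, so each gene was given a spread shared with genes of like expression and none of its own.

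Leaving out each library in turn gave 3 to 632 genes in DND-41, 0 to 1430 in MOLT-4, 0 to 537 shared, an r of 0.33 to 0.40, 49 to 138 differences, 2 to 8 lists in DND-41 and 3 to 7 in MOLT-4. The lone library of an arm is then assumed to vary like the other arm. In the fits per line the prior degrees of freedom were between 2.31 and 4.33 without an ACBI-1 library and infinite without a DMSO library. In the fit of all 8 libraries the ranges were 692 to 1264, 712 to 942 and 370 to 551 genes and an r of 0.158 to 0.267. For single genes and lists, counting each once per library left out, 417 of 1648 comparisons lost and 26 gained a call in the fits per line and of the difference, and 147 and 14 of 1000 for the lines in the fit of all 8. CXCR4 in DND-41, and NOTCH1, PTGDR2 and SEMA7A for the difference, kept their call under every alternative run. Direction reversed for mitochondrially encoded genes in DND-41 without ACBI-1 replicate 1 (-0.21, up to 0.28 without another library), MT-ND6 in DND-41 in the fit of all 8 without that library (-0.44, up to 0.92), and the TRBV20-1 difference between lines after subtraction (-1.08) or without DND-41 DMSO replicate 2 (-0.15, up to 4.88). The cause was not settled for any of these. Depth limits genes near 1 CPM, with about 20 reads per library.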

Other observations

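Of the tests in this part, those of symbol families and of a stray read level common to all DND-41 libraries were chosen only after the results were seen. So was the GC correction. The others were set before their results, among them that of the NOTCH1 target list for a difference between lines.

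Of 84 families of genes that share a symbol stem, with at least 15 tested members each, the immunoglobulin heavy chain variable segments (IGHV) were higher with ACBI-1 in DND-41. Of 35 tested segments 9 rose and 0 fell, with a median of 0.40 (camera, adjusted p = 0.000785, 0.00185 after the GC correction, but 0.792 with an estimated correlation between genes), and in MOLT-4 4 of 19 rose and 0 fell (adjusted p = 0.143). These segments are near-identical copies that can share reads, so single members are uncertain. tRNA methyltransferase genes (TRMT) were higher in DND-41, with 3 of 15 risen and 0 fallen (camera, adjusted p = 0.0311; 0.792 with an estimated correlation), and mitochondrial ribosomal protein genes (MRPL) in MOLT-4, with 3 of 48 risen and 0 fallen and a median of 0.10 (camera, adjusted p = 0.017; 0.844 with an estimated correlation). No family was called in both lines.

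Some markers of other cell types were present without changing. CD79A, a component of the B-cell receptor, stood at 1732 CPM in DND-41 DMSO and 12.3 CPM in MOLT-4 DMSO, IGLL1, a surrogate light chain gene, at 487 and 138 CPM, and EBF1, a B-lineage transcription factor, at 12.3 CPM in DND-41 and no counts in MOLT-4 DMSO. None of these 3 was called with ACBI-1 in a line where it was tested. Of the B-cell list VPREB1 fell in MOLT-4 (-0.79 ± 0.17, edgeR adjusted p = 0.00291), a call lost with DESeq2. Of the 16 genes called in opposite directions, chosen after their values were seen, NRROS (0.42 and -0.24 in DND-41 and MOLT-4) and CCM2 (-0.38 and 0.39) were among those with the highest expression in both lines.

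DND-41 DMSO replicate 2 held more reads than the other DND-41 libraries of genes that are at least 50 times lower in DND-41 than in MOLT-4. Its 48 MOLT-4 markers exceeded the other DND-41 libraries by a median of 0.564% of their MOLT-4 level, and 45 were highest in it. An equal level of stray reads in all DND-41 libraries is argued against, since the median was 7.53 times that of the next library. That ratio restates the pattern itself, and its limit was set after the values were seen, so it is not a separate test. MOLT-4 RNA or reads in that library is a candidate explanation, and 167 further MOLT-4 genes had a median of 0.746% there against 0 in each of the other 3 libraries. Of them 65.3% were highest there, between the 80% set beforehand for this cause and the 50% set against it. That test cannot decide it, because these genes, at 10 to 50 CPM in MOLT-4, would have few reads at such a share. DMSO replicate 2 also came last in the order of libraries and so lost every tie. No biological explanation was tested, and in MOLT-4 DMSO replicate 2 the 31 DND-41 markers had an excess of 0.209%, with 18 highest in it.

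The hypothesis that zinc finger (ZNF) genes rose as a family, raised by ZNF333 and ZNF341, was not borne out, as camera gave a p of 0.153 in MOLT-4 and 0.0822 in DND-41. In DND-41 39 of 461 rose and 21 fell, and in MOLT-4 28 of 449 rose and 29 fell. Their medians of 0.04 and 0.02 nevertheless lay at percentiles 100 and 99.5 of random lists matched on GC content, length and expression, which argues against these properties as the source of the small shift. The hypothesis that NOTCH1 target genes fell more in MOLT-4 than in DND-41 was not borne out either (camera p of 0.0831 for the difference, over 17 genes). Nor was the hypothesis that genes more highly expressed in 1 line at baseline fell more in that line, since the Spearman rho across 9309 genes was 0.0234 and 0.0388 in the 2 splits of the DMSO replicates, where a value of at most -0.1 had been set.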
